A study of Marchantia polymorpha and Arabidopsis thaliana and Oryza sativa Japonica Group with 80 samples.

How the data were processed

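The series holds 80 samples, of which 68 are RNA libraries in 5 experiments and 12 are chromatin immunoprecipitation samples, not used here. Per the labels, each library comes from 7-day-old plants treated with 100 mM NaCl for the time its label gives. Per the labels, RNA was extracted with a plant RNA kit and libraries were made by standard Illumina protocols. The submitters' processing notes name STAR and the TAIR10 genome for every sample, whatever its organism. The STAR version, the annotation and the references for rice and Marchantia are not given in the sources used here.

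For the Arabidopsis time course the deposited values are expected counts, 1 table of 24060 genes in which 1.42% of values, in 973 genes, are not whole; they were rounded. For the other 4 experiments the deposited values are counts, 1 sheet per library with 3 count columns (either strand, and each strand) and 4 summary lines for reads that are unmapped, multimapping, outside features or ambiguous. The column for either strand was used in the mutant experiment, whose reads fall on both strands alike, and the column for the opposite strand in both Marchantia experiments. For rice a combined table was used, which equals the opposite strand column of each library. The summary lines were left out of the depth. The libraries were matched to groups through the deposited condition sheets and the sample labels. The sheets for rice and for the second Marchantia experiment give times and do not name salt. They write the same unexplained code before each time, Cnt for all 9 rice libraries and Crt for all 9 of the second Marchantia experiment, and no other code is used. The sheet of the mutant experiment, by contrast, writes Control at 0 h and Salt at 2 and 24 h. Salt in these 2 experiments therefore rests on the protocol in the labels alone.

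The tables differ in reach. The time course table lacks 14118 genes of the mutant experiment's 34218 and shares 20100 with it. The rice table has 91080 features, of which 452 tested ones have identifiers of another annotation. The Marchantia tables have 19755 gene numbers, each tested one matched to a Mapoly locus through a deposited sheet (11257 of 11257 and 9896 of 9896). Strand shares differ by experiment: of reads counted on a strand, 49.8% to 50.4% lay on the opposite strand in the mutant experiment, 84.3% to 85.9% in rice and 98.6% to 99.1% in Marchantia. Unmapped reads made up 3.95% to 5.87% in the mutant experiment, 10.8% to 27.3% in rice, 10.6% to 14.3% in the Marchantia time course and 10.9% to 27.6% in the second Marchantia experiment. No pair of libraries was identical.

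Counts were analysed with edgeR 4.0.16 in R 4.3.3. Within each experiment genes were kept by filterByExpr with the groups, libraries were scaled by TMM, and a quasi-likelihood model with 1 coefficient per group was fitted to all libraries. Each contrast was tested two-sided, with Benjamini-Hochberg adjustment over the genes tested and calls at an adjusted p below 0.05. SE are the absolute log2 fold change divided by the root of the quasi-likelihood F. CPM are counts scaled to the TMM-scaled library size, and log2 CPM carry a prior count of 2. The contrasts were each time against 0 h, the labelled mutant against Col-0 at each time, and the interaction of genotype and salt. Where a group holds 0 counts, a fold is given as a lower bound against a floor of 3 counts over the group, which covers counting error only.

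Gene lists were fixed before the data were examined, 20 for Arabidopsis (386 genes) and 4 for rice (30 genes). The Arabidopsis lists cover ABA response and dehydrins, ABA synthesis and signalling, ABA receptors, ion transport, proline and osmolytes, stress transcription factors, the WRKY family, camalexin, salicylic acid, jasmonate, ethylene, redox, photosynthesis, the cell cycle, wall expansion, suberin, root hairs, the clock, heat shock, and senescence with starvation. Root hairs were tested in the time course only. The rice lists cover ABA response and dehydrins, transport and osmolytes, transcription factors with an ABA synthesis gene, and photosynthesis. Gene names come from these lists, since the tables do not pair identifiers with names. Each list was tested for a net shift one way with fry (limma 3.58.1) on log2 CPM, adjusted over all lists and contrasts of the experiment (140 tests in the time course, 171 in the mutant experiment, 8 in rice). The test is self-contained: it does not compare the list with other genes. Camera with an estimated correlation was run beside it, and of the 23, 14 and 3 calls by fry in these experiments 0, 0 and 1 held with it.

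The rule for named genes, also fixed before the data were examined, takes WRKY25 and WRKY33, up to 4 members of each list that were called in the most contrasts, and the 5 largest rises and falls per contrast among called genes whose groups do not overlap and whose mean is at least 5 CPM. Of genes without a name it takes at most 2 that rose and 2 that fell, and for genotype contrasts the 10 smallest p-values. WRKY18, WRKY40 and WRKY60 fall under this rule and were singled out after their values were seen. Some stress genes of the 0 h libraries, and the WRKY25 and WRKY33 values of the time course were added after values were seen. The named genes gave 658 called values. In 373 of 373 of the time course, 234 of 245 of the mutant experiment, 27 of 27 of rice and 13 of 13 of the second Marchantia experiment all treated libraries lay beyond all 0 h libraries, or those of one genotype beyond those of the other. The rule itself asks this of the largest changes. Of all genes tested, 48.8% to 66.5% had it in the time course and 27.3% to 40.1% in the salt contrasts of the mutant experiment. These shares were 3.6% to 7.2% between genotypes, 15.9% and 33.8% in rice, and 36.1% and 57.6% in the second Marchantia experiment.

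Alternatives set before the data were examined were RLE scaling, no filter on low counts, DESeq2 1.42.0, a fit of only the groups of the contrast, a replicate block, leaving out each library in turn, camera for the lists, and a minimum of 5 CPM for correlations between experiments. Chosen after seeing the data were fits with replicates 1 and 2 only or 1 and 3 only in the mutant experiment, and with replicates 2 and 3 only in rice and in the second Marchantia experiment. The replicate number pairs libraries in the mutant experiment, where the sample sheet names it as the batch and 18 of 18 libraries were closest to one of their own number once group means were removed, and in the second Marchantia experiment (9 of 9). In rice 5 of 9 were, in the Arabidopsis time course 14 of 16 and in the Marchantia time course 16 of 16, where the 2 libraries of a time mirror each other once their mean is removed.

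The procedure was tested on counts simulated with the gene means, depths and trended dispersions of each experiment, into which changes were placed. Each set was drawn once, with independent genes and no batches, so the shares below may not hold in the real libraries. At 24 h in the Arabidopsis time course edgeR found 95.5% of 4-fold and 59.7% of 2-fold changes with 5.3% false calls, in rice 93.9% and 47.8% with 2.9%, and in the second Marchantia experiment 93.9% and 76.1% with 7.6%. Between the genotypes at 0 h it found 89.4% and 37.3% with 4.5%, and in the Marchantia time course 25.8% and 1.5% with 5.3%. A list of 15 raised genes was found in each of these 5 comparisons (fry p at most 8.43e-06, unadjusted). A list of 15 unchanged genes had a fry p of at least 0.316 in 4 of them, but 0.00459 between the genotypes at 0 h (0.0369 by camera with an estimated correlation), so the list tests can call an unchanged list there. Tables were handled in Python 3.11.15 with pandas 2.3.3 and NumPy 2.4.6, and figures drawn with matplotlib 3.10.9.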

Results

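RNA was sequenced from 68 libraries of young plants before and after a change to medium with 100 mM NaCl, in 5 experiments on 3 species. For rice and the second Marchantia experiment the salt is named by the protocol alone, and their sheets write one code, Cnt or Crt, for every library. The Arabidopsis time course holds 7-day-old Col-0 seedlings, the common laboratory strain, at 0 h and at 7 later times from 1 to 72 h (1, 3, 6, 12, 24, 48, 72), with 2 libraries per time and 18404537 to 24148376 counted reads per library. The mutant experiment holds Col-0 seedlings and seedlings labelled wrky25/33, a line named for the loss of the transcription factors WRKY25 and WRKY33, at 0, 2 and 24 h, with 3 libraries per group and 17431071 to 41887006 counted reads. The rice experiment holds seedlings of the line NB at 0, 2 and 24 h, with 3 libraries per time and 10142302 to 29473283 counted reads. Gemmalings of the liverwort Marchantia polymorpha (strain Tak1) were sampled at the 8 times of the Arabidopsis course, with 2 libraries per time and 18569851 to 24860700 counted reads. A second Marchantia experiment covers 0, 2 and 24 h, with 3 libraries per time and 7903835 to 11475449 counted reads. The p-values measure the spread between libraries, which the series calls biological replicates without saying how each was grown. The 12 chromatin immunoprecipitation samples of the series were not analysed here.

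The Arabidopsis time course asks how the seedling transcriptome moved over 72 h of salt. Neither Arabidopsis experiment holds an untreated library after 0 h. Their changes are those since 0 h, and salt cannot be told apart from time of day, handling or growth. Within 1 h, transcripts of dehydration-protective proteins rose by more than any other list tested at that time. Changes are log2 fold changes against 0 h, each with its SE, and the libraries of every called gene named with one lay wholly above or wholly below the 0 h libraries. So did those of 48.8% to 66.5% of all genes tested, depending on the time. ERD10 (AT1G20450), a dehydrin, went from 32.4 to 1430 CPM (counts scaled to library size; log2 fold change 5.47 ± 0.36, adjusted p = 3.01e-06). RD29A (AT5G52310), a reporter of dehydration and abscisic acid (ABA), rose by 5.91 ± 0.46 (adjusted p = 7.68e-06) and peaked at 3 h with 2370 CPM against 31.3 at 0 h. At 3 h COR15A (AT2G42540), a chloroplast-protecting protein, rose by 10.61 ± 1.32 (adjusted p = 0.000211), the lipid transfer protein LTP3 (AT5G59320) by 8.64 ± 0.68 (adjusted p = 1.1e-05) and KIN2 (AT5G15970) by 6.16 ± 0.37 (adjusted p = 2.62e-06). Of the 17 ABA response and dehydrin genes tested, 12 rose at 1 h, 15 at 3 h, 11 at 6 h, 7 at 12 h and 9 at 24 h, and edgeR called none lower at these times. Adjusted over the list alone, 12, 17, 13, 10 and 10 rose and none fell. The fry adjusted p of the list was 0.000216, 2.82e-05, 0.000317, 0.00666 and 0.0374 at the same times. With an estimated correlation the adjusted p was 0.222 at 1, 3 and 6 h, 0.394 at 12 h and 0.758 at 24 h. Their median log2 fold change was 3.46 at 1 h, 5.37 at 3 h, 2.66 at 6 h and 1.36 at 24 h. At 48 and 72 h 2 and 4 members rose, and the list was no longer called (fry adjusted p = 0.319 and 0.0871).

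The ABA pathway itself turned over in the same hours. Phosphatases that restrain ABA signalling rose at 1 h, ABI2 (AT5G57050) by 2.87 ± 0.18 (adjusted p = 1.95e-06) and HAI1 (AT5G59220) by 6.08 ± 0.68 (adjusted p = 8.44e-05). Of 14 genes of ABA synthesis and signalling, 10 rose at 1 h and 11 at 3 h, and none was called lower by edgeR (11 and 12 up, 0 down, adjusted over the list alone). Their medians were 1.95 and 1.39. Fry gave an adjusted p of 0.00109 and 0.00132, and the adjusted p was 0.447 at both times with an estimated correlation. Among 8 ABA receptor genes, PYL6 (AT2G40330), PYL4 (AT2G38310) and PYL5 (AT5G05440) fell at 1 h, with log2 fold changes of -3.78 ± 0.30, -2.63 ± 0.28 and -1.95 ± 0.20 (adjusted p = 9.36e-06, 5.76e-05 and 5.53e-05). PYL7 (AT4G01026) rose by 2.49 ± 0.14 (adjusted p = 1.31e-06). With 2 receptors up and 5 down at 1 h the list did not move one way (fry adjusted p = 0.266). P5CS1 (AT2G39800), which makes proline, a protective solute, rose at every time tested, by 4.80 ± 0.29 at 3 h (adjusted p = 2.62e-06) and still by 1.45 ± 0.25 at 72 h (adjusted p = 0.00205). Its call at 12 h ended without 0 h replicate 1 or 2 (adjusted p = 0.0575 and 0.0651). GOLS1 (AT2G47180), which starts the synthesis of raffinose sugars, rose by 1.60 ± 0.19 at 1 h (adjusted p = 0.000124), and SIP2 (AT3G57520), which breaks them down, fell (log2 fold change -1.73 ± 0.23, adjusted p = 0.000259). Of 13 proline and osmolyte genes, 5 rose and 1 fell at 1 h, 6 and 1 at 3 h, and 2 and 1 at 6 h. Adjusted over the list alone these were 7 and 2, 9 and 1, and 4 and 1. The list moved up by fry (adjusted p = 0.0006, 0.000238 and 0.00666), which was lost with an estimated correlation (adjusted p = 0.315, 0.222 and 0.563).

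Other lists were also called within the first 12 h. Jasmonate genes rose at 1 h, among them the synthesis enzymes LOX3 (AT1G17420; 2.84 ± 0.34, adjusted p = 0.000146) and AOS (AT5G42650; 2.28 ± 0.37, adjusted p = 0.00126) and the regulator MYC2 (AT1G32640; 1.74 ± 0.18, adjusted p = 3.92e-05). In this list 9 of 13 genes rose and 1 fell at 1 h (10 up and 1 down adjusted over the list alone). Its median was 1.74, with a fry adjusted p of 0.00568 and an adjusted p of 0.684 with an estimated correlation. The heat shock factor HSFA2 (AT2G26150) rose from 0.864 to 20.8 CPM at 1 h (log2 fold change 4.59 ± 0.47, adjusted p = 4.43e-05), and HSP90.1 (AT5G52640) rose with it by 3.37 ± 0.39 (adjusted p = 9.65e-05). Of 7 heat shock genes, 4 rose at 1 h, also adjusted over the list alone (median 2.35). The fry adjusted p was 0.00666, or 0.692 as an adjusted p with an estimated correlation. At 3 h the vacuolar sodium transporter gene NHX2 (AT3G05030) rose by 1.49 ± 0.24 (adjusted p = 0.00122). Of 12 ion transport genes 7 rose and 1 fell (8 up and 1 down adjusted over the list alone). This list had a fry adjusted p of 0.043 and an adjusted p of 0.798 with an estimated correlation. ASFT (AT5G41040), which makes the aromatic part of suberin, a water barrier of roots, rose by 4.48 ± 0.36 at 3 h (adjusted p = 1.25e-05). It was 1 of 2 suberin genes to rise of 5, also adjusted over the list alone, with a fry adjusted p of 0.0179 and an adjusted p of 0.798 with an estimated correlation. MCM3 (AT5G46280), a DNA replication gene of the cell cycle list, fell at 3 h (log2 fold change -1.28 ± 0.24, adjusted p = 0.00356). This list had 6 of 18 genes down at 3 h and 3 at 12 h (7 and 9 adjusted over the list alone), and edgeR called none up. Its fry adjusted p was 0.0353 and 0.0179, with adjusted p of 0.798 and 0.563 with an estimated correlation.

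Growth and photosynthesis genes and a suberin gene were also called at later times. The light-harvesting gene LHCB1.4 (AT2G34430) fell at 48 h (log2 fold change -2.18 ± 0.37, adjusted p = 0.00203) and at 72 h, from 7330 to 1380 CPM (-2.40 ± 0.38, adjusted p = 0.0012). Of 31 nuclear photosynthesis genes, 20 fell and 0 rose at 48 h and 20 fell and 0 rose at 72 h (0 up and 28 down adjusted over the list alone, at both times). The list test itself missed its threshold at 48 h (median -0.80, fry adjusted p = 0.0562) and at 72 h (median -0.85, fry adjusted p = 0.0508). CYP86A1 (AT5G58860), which makes the fatty part of suberin, rose by 2.64 ± 0.36 at 12 h (adjusted p = 0.00268) and 3.53 ± 0.36 at 72 h (adjusted p = 0.000105). The 5 suberin genes as a list did not follow it. Their medians in replicates 1 and 2, relative to 0 h, were 0.05 and 0.05 at 12 h and -0.84 and -0.61 at 24 h. At 48 h they were -1.03 and -0.43, and at 72 h -0.31 and 0.24. The mitotic kinase AUR2 (AT2G25880) fell at 24 h (log2 fold change -1.90 ± 0.17, adjusted p = 0.000185). The expansin gene EXPA10 (AT1G26770) rose by 3.51 ± 0.34 at 48 h (adjusted p = 0.000109). The wall enzyme gene XTH4 (AT2G06850), down at 3 h (log2 fold change -3.49 ± 0.32, adjusted p = 3.22e-05), was still lower at 72 h (-2.10 ± 0.30, adjusted p = 0.000843). Of 13 wall genes, 4 rose and 1 fell at 6 h, 1 and 7 at 48 h, and 1 and 6 at 72 h, or 5 and 1, 1 and 7, and 1 and 6 adjusted over the list alone. Their medians were 0.49, -1.02 and -0.44. The fry adjusted p was 0.0353, 0.0424 and 0.0353, and the adjusted p was 0.798 at each time with an estimated correlation. The 3 root hair markers tested were all lower at 24 h and at 48 h, also adjusted over the list alone, and 1 was at 72 h. The list had a fry adjusted p of 0.0353 at 24 h and 0.00666 at 48 h, and adjusted p of 0.761 and 0.692 with an estimated correlation. COBL9 (AT5G49270) of this list stood at 0.064 CPM at 48 h and 3.21 at 0 h (adjusted p = 0.00164).

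The WRKY family, plant-specific transcription factors, was called as a list at 1 h and 72 h. At 1 h 11 of 47 members rose and 3 fell, also adjusted over the list alone, led by WRKY17 (AT2G24570) with 2.19 ± 0.13 (adjusted p = 1.37e-06). At 72 h 22 rose and 3 fell (24 up and 4 down adjusted over the list alone), WRKY70 (AT3G56400) among the latter with -2.13 ± 0.47 (adjusted p = 0.00705). Medians were 0.41 and 0.84. At 72 h replicate 2 lay higher than replicate 1 in this list (1.03 and 0.60 relative to 0 h), and also in the heat shock (1.29 and -0.39), stress transcription factor (0.81 and -0.16) and salicylic acid lists (0.83 and -0.03). The fry adjusted p was 0.0353 at 1 h and 0.00568 at 72 h, with adjusted p of 0.798 and 0.684 with an estimated correlation. WRKY25 (AT2G30250) rose by 1.41 ± 0.21 at 72 h (adjusted p = 0.000893). It was also called higher at 1, 12, 24 and 48 h, by 0.76 ± 0.21, 0.97 ± 0.21, 0.81 ± 0.21 and 0.92 ± 0.21 (adjusted p = 0.026, 0.0211, 0.0239 and 0.00865). These calls ended without any 1 of the 4 libraries at 1 h (adjusted p from 0.0726 to 0.124) and 24 h (0.0915 to 0.139). At 12 h the call ended without 0 h replicate 1 or 2 or 12 h replicate 2 (0.133, 0.142 and 0.119), and at 48 h without replicate 2 of 0 h or 48 h (0.0645 and 0.0517). WRKY33 (AT2G38470) rose by 1.69 ± 0.43 at 72 h (adjusted p = 0.0143), a call that ended without 0 h or 72 h replicate 2 (adjusted p = 0.118 and 0.224). At 3 and 6 h it stood at -0.82 ± 0.43 and -0.98 ± 0.43 (adjusted p = 0.241 and 0.202), with both libraries below those at 0 h. ACS2 (AT1G01480), an ethylene synthesis enzyme, rose by 3.11 ± 0.57 at 1 h (adjusted p = 0.00259) and 4.21 ± 0.58 at 72 h (adjusted p = 0.000656). The pathogenesis gene PR1 (AT2G14610) fell at 48 h (log2 fold change -2.41 ± 0.49, adjusted p = 0.00496). Of genes for ethylene response factors 2 are named here that were lower than at 0 h, ERF104 (AT5G61600) at 1 h (log2 fold change -2.70 ± 0.30, adjusted p = 7.28e-05) and ERF105 (AT5G51190) at 6 h (-4.24 ± 0.63, adjusted p = 0.00267). The stress transcription factor list as a whole had 10 of 22 genes up and 2 down at 1 h (fry adjusted p = 0.0672) and 2 up and 7 down at 24 h (fry adjusted p = 0.318).

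**Figure D1:**
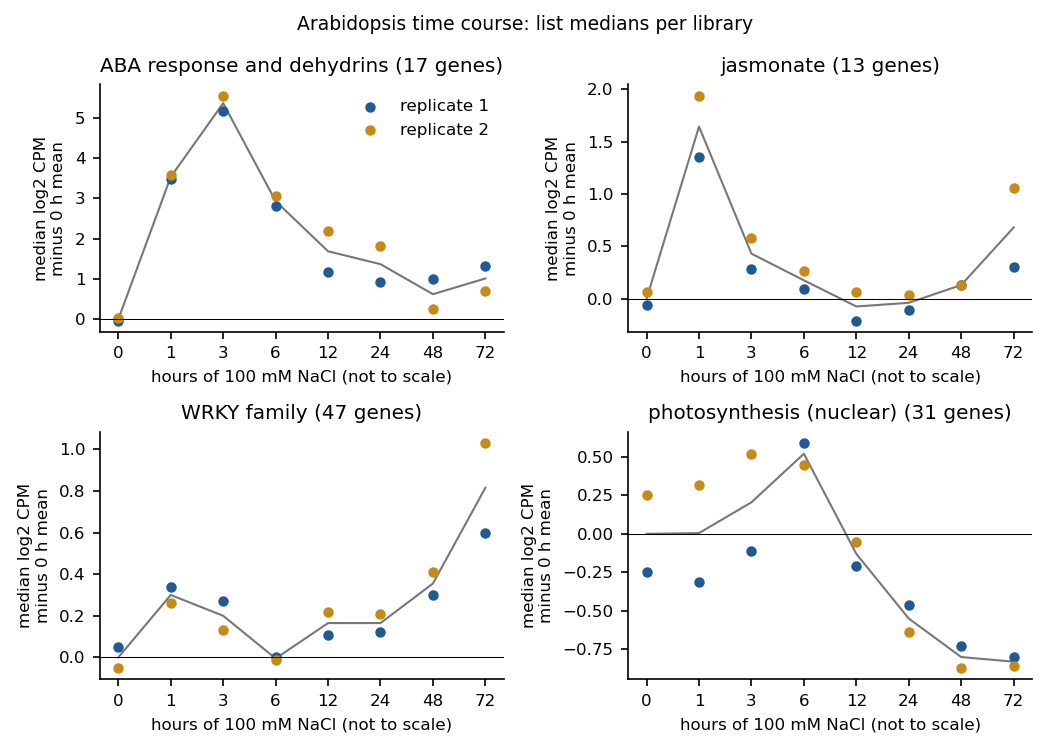
Median log2 CPM of 4 gene lists in each library of the Arabidopsis time course, relative to the mean of the 0 h libraries (y axis, log2), by hours of salt (x axis, not to scale). Points are libraries, with 2 replicates per time, and lines join the means. The ABA response list peaks at 3 h, at 5.18 and 5.55, and the photosynthesis list lies at -0.80 and -0.86 at 72 h.

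Over the 15407 genes tested, 1346 rose and 839 fell at 1 h, 1310 and 1008 at 3 h, 656 and 345 at 6 h, 400 and 253 at 12 h, 993 and 947 at 24 h, 1603 and 1784 at 48 h, and 1890 and 1933 at 72 h (edgeR, n = 2 per time). Some lists were called at no time. Of these, 4 of 7 camalexin genes rose at 72 h (fry adjusted p = 0.0762), 3 of 10 clock genes at 1 h (0.0508) and 4 of 12 redox genes at 72 h (0.225). Of 9 salicylic acid genes 3 rose at 1 h (0.0568), of 5 senescence genes 3 rose at 72 h (0.0871), and of 7 ethylene genes 2 rose and 2 fell at 72 h (0.714). With a replicate block 6 list calls of this course narrowly ended: ion transport at 3 h (fry adjusted p = 0.0502), wall genes at 6, 48 and 72 h (0.0502, 0.0575 and 0.0502), and ABA response and root hair genes at 24 h (0.0502 and 0.0502). Stress transcription factors at 1 h and suberin genes at 6 h were called only with it (0.0323 and 0.0152; adjusted p = 0.799 and 0.785 with an estimated correlation). With only the groups of the contrast fitted, 1358 genes were called at 1 h and 2011 at 6 h, and fewer at 72 h than at 6 h, as given below. With 2 libraries per time the counts leaned on single libraries. Without 0 h replicate 1 or 2 the counts were 1288 and 1201 at 1 h, 1230 and 1231 at 3 h, 184 and 338 at 6 h, 112 and 129 at 12 h, 960 and 463 at 24 h, 2023 and 1279 at 48 h, and 2281 and 1431 at 72 h. Without replicate 1 or 2 of the treated time they were 204 and 369 at 6 h, 234 and 299 at 12 h, 821 and 406 at 24 h, and 2172 and 1309 at 48 h. Without replicate 2 they were 1379 at 3 h and 1858 at 72 h.

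**Figure D2:**
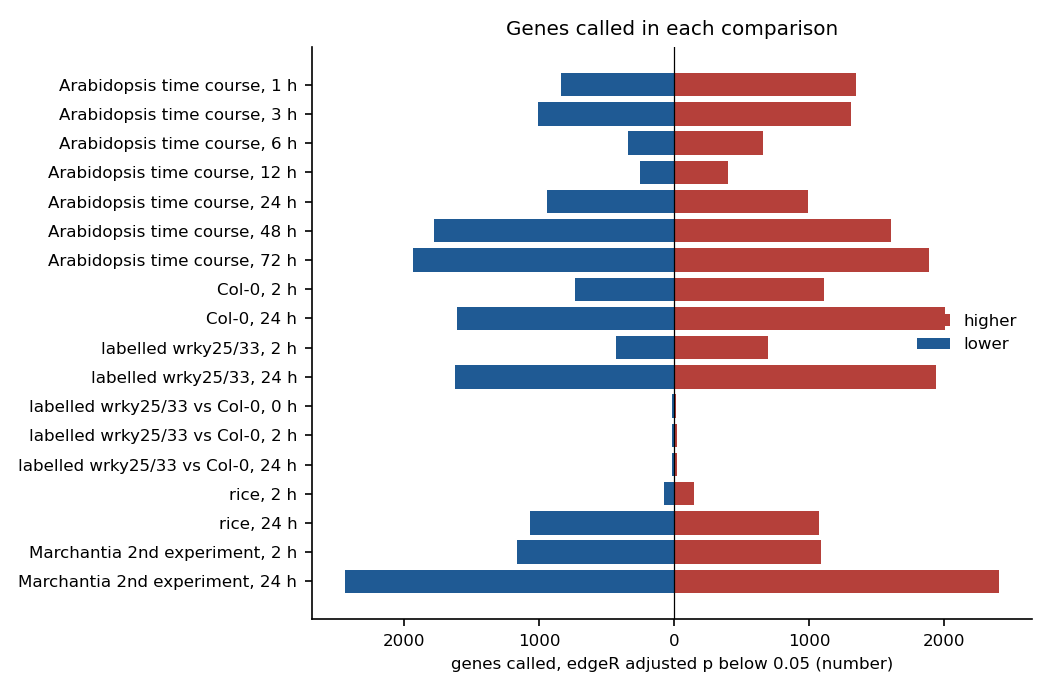
Genes called by edgeR at adjusted p below 0.05 in each comparison (x axis, number of genes), with those higher to the right of 0 and those lower to the left. Bars are the counts of the contrast named on the y axis, against 0 h unless 2 genotypes are named; the Marchantia time course, with 0 called at each time, and the interactions, also 0, are not drawn.

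The mutant experiment asks how Col-0 seedlings and seedlings labelled wrky25/33 change over the same hours of salt. What is called their salt response is again the change since 0 h, with no untreated library at later times. At 2 h both groups raised the dehydrin programme to a similar height. LEA4-5 (AT5G06760), a late embryogenesis protein, rose by 7.82 ± 0.98 in Col-0 and 7.25 ± 0.95 in the labelled line (adjusted p = 0.000176 and 0.000379). LTP3 rose by 8.34 ± 0.93 and 7.26 ± 0.91 (adjusted p = 7.45e-05 and 0.000255). LEA7 (AT1G52690) had 0 counts in Col-0 at 0 h and 433 at 2 h, at least 201-fold higher against a floor of 3 counts over the group. Of 20 ABA response genes, 18 rose in Col-0 and 17 in the labelled line, and 20 in each adjusted over the list alone. Their medians were 3.43, the same with LEA7 at its bound, and 3.73. The fry adjusted p was 0.00142 and 0.00164, and the adjusted p was 0.329 in both with an estimated correlation. P5CS1 rose by 4.89 ± 0.42 and 4.54 ± 0.42 (adjusted p = 1.25e-05 and 3.41e-05). HB7 (AT2G46680), an ABA-induced regulator, rose by 4.31 ± 0.43 and 4.03 ± 0.42 (adjusted p = 2.78e-05 and 5.63e-05). The receptor gene PYL6 fell in both (log2 fold change -4.68 ± 0.60 and -3.54 ± 0.56, adjusted p = 0.000201 and 0.00145), as at 1 h in the time course. So did PYR1 (AT4G17870; -1.43 ± 0.23 and -1.62 ± 0.24, adjusted p = 0.00146 and 0.000914).

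The lists called at 2 h were the same in both groups. Of 21 ABA synthesis and signalling genes 15 rose in Col-0 and 14 in the labelled line (18 and 17 adjusted over the list alone). The fry adjusted p was 0.00179 and 0.00214, and the adjusted p 0.361 and 0.329 with an estimated correlation. Of 9 ABA receptor genes 5 fell in Col-0 and 4 in the labelled line (2 up and 5 down in each adjusted over the list alone). Here the fry adjusted p was 0.0103 and 0.0125, and the adjusted p 0.858 in both with an estimated correlation. Of 15 osmolyte genes 6 rose and 1 fell in each (7 and 2 in Col-0, 9 and 2 in the labelled line adjusted over the list alone). For these the fry adjusted p was 0.0125 and 0.0143, and the adjusted p 0.858 in both with an estimated correlation. Of 8 suberin genes 4 rose in Col-0 and 4 in the labelled line (5 and 7 adjusted over the list alone). Fry gave an adjusted p of 0.00164 and 0.00214, against an adjusted p of 0.329 in both with an estimated correlation. The suberin regulator MYB41 (AT4G28110) reached 3.19 CPM in Col-0 and 3.57 in the labelled line, from 0.0305 and 0.168 at 0 h.

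At 24 h the dehydrin list was not called, with members up and down, and genes of carbon starvation and detoxification were up. ASN1 (AT3G47340), an asparagine synthetase induced by sugar shortage, rose by 3.98 ± 0.83 in Col-0 and 3.62 ± 0.81 in the labelled line (adjusted p = 0.00522 and 0.00836), from 93.6 to 1470 CPM in Col-0. DIN2 (AT3G60140), a dark-induced glucosidase, rose by 4.85 ± 1.02 and 5.05 ± 1.03 (adjusted p = 0.00552 and 0.0052). SAG13 (AT2G29350), a senescence marker, rose by 5.52 ± 0.86 and 3.57 ± 0.76 (adjusted p = 0.00104 and 0.00657). Of 11 senescence and starvation genes, 9 rose in the labelled line and 8 in Col-0 (9 in each adjusted over the list alone). The list was called in the labelled line (fry adjusted p = 0.0275, adjusted p = 0.858 with an estimated correlation). In Col-0 it missed the threshold (fry adjusted p = 0.0558, and 0.00141 with a replicate block, or 0.962 as an adjusted p with an estimated correlation). The glutathione transferase GSTU24 (AT1G17170) rose by 3.78 ± 0.49 and 3.33 ± 0.48 (adjusted p = 0.000417 and 0.000833). Of 16 redox genes 8 rose and 1 fell in Col-0 (9 up and 1 down adjusted over the list alone), and 8 and 0 in the labelled line (8 up and 0 down adjusted over the list alone). Fry called both (adjusted p = 0.022 and 0.026), with an adjusted p of 0.858 in both with an estimated correlation. P5CS1 stayed higher by 2.66 ± 0.38 and 2.78 ± 0.39 (adjusted p = 0.000736 and 0.000654). Of 15 osmolyte genes 4 rose in the labelled line (6 up and 0 down adjusted over the list alone), with a fry adjusted p of 0.031 and an adjusted p of 0.858 with an estimated correlation. In Col-0 5 rose (fry adjusted p = 0.0558, and 0.00384 with a replicate block, or 0.962 as an adjusted p with an estimated correlation). Replicate 2 was lowest: the osmolyte medians of replicates 1, 2 and 3, relative to Col-0 at 0 h, were 1.5, 0 and 1.33 in Col-0. In the labelled line they were 1.47, 0.6 and 1.34. The jasmonate enzyme AOS fell in both (log2 fold change -1.59 ± 0.37 and -2.07 ± 0.37, adjusted p = 0.00889 and 0.00268). Of the ABA response genes 5 rose and 3 fell in Col-0 (fry adjusted p = 0.992), and 3 and 3 in the labelled line (0.992). RD20 (AT2G33380), of this list, a calcium-binding protein induced by drought, was still higher by 7.09 ± 1.03 and 6.57 ± 1.00 (adjusted p = 0.000736 and 0.000968). WRKY25 rose by 1.33 ± 0.33 in Col-0 and 1.24 ± 0.33 in the labelled line (adjusted p = 0.013 and 0.0183). These calls ended in Col-0 without 0 h replicate 2 or 24 h replicate 3 (adjusted p = 0.0621 and 0.0825) and in the labelled line without 0 h replicate 2 or 3 or 24 h replicate 1 or 3 (0.0769, 0.0536, 0.0515 and 0.0779).

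Some lists were called only when the 3 batches, which the sample sheet names and which hold the replicate of each number, were fitted as a replicate block. With an estimated correlation the adjusted p was 0.962 for each of them. At 24 h 1 of these was photosynthesis, with 3 of 37 genes up in Col-0 and 5 in the labelled line (fry adjusted p = 0.493 and 0.479, blocked 0.00685 and 0.00523). The others at 24 h were the cell cycle, with 5 and 6 of 23 genes down (0.0836 and 0.126, blocked 0.0131 and 0.017), and the clock (blocked 0.0352 and 0.0164). The cell cycle fall was small in replicate 2, with list medians at 24 h of -1.75, -0.13 and -1.80 in Col-0 and -1.91, -0.55 and -1.28 in the labelled line for replicates 1, 2 and 3. They also included salicylic acid genes in Col-0, 3 of 11 down (0.209, blocked 0.0143). Ion transport was called with the block in the labelled line at 24 h (0.242, blocked 0.00523) and in both groups at 2 h (0.349 in Col-0, blocked 0.0165 and 0.0164), as was ABA synthesis in the labelled line at 24 h (0.167, blocked 0.0469). No call came from stress transcription factors at 2 h, with 10 of 32 up and 1 down in Col-0 (fry adjusted p = 0.469), or from WRKY genes at 24 h, with 6 of 51 up and 8 down (0.992). From 0 to 2 h the stress list medians of Col-0 replicates 1, 2 and 3 went from -0.1 to -0.12, -1.19 to 0.57 and 1.41 to 1.07. The high 0 h value of replicate 3 thus weighs on that test. The camalexin, wall, ethylene, heat shock and jasmonate lists were not called either, with 0, 1, 3, 0 and 1 genes up and 1, 4, 2, 0 and 2 down in Col-0, at 2 h for wall genes and at 24 h for the others. Heat shock genes were high in replicate 1, with medians of 0.88 at 0 h and 1.87 at 2 h in Col-0. In the labelled line its medians were 2.39 and 2.01. Replicates 2 and 3 lay between -0.87 and 0.37 at these times. Fits with replicates 1 and 2 only, given below, keep this batch.

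Over the 19316 genes tested, 1112 rose and 739 fell in Col-0 at 2 h and 2006 and 1610 at 24 h, and in the labelled line 697 and 434 at 2 h and 1942 and 1629 at 24 h (edgeR, n = 3). With the replicate block these totals, 1851, 3616, 1131 and 3571, became 4823, 6895, 3475 and 7021. With only the groups of the contrast fitted they were 1404, 61, 922 and 3628. With replicates 1 and 2 only, without the batch of high stress transcription factors at 0 h, they were 473, 349, 173 and 441. With replicates 1 and 3 only, which leaves out a batch whose 24 h libraries stood apart, they were 631, 3444, 345 and 2193. For Col-0 the count at 2 h was 933 without 0 h replicate 2 and 820 without 2 h replicate 3. At 24 h it was 1916 or 2153 without 0 h replicate 2 or 3 and 1650, 6052 or 1664 without 24 h replicate 1, 2 or 3. For the labelled line the count at 2 h was 646 or 578 without 0 h replicate 2 or 3 and 710 or 562 without 2 h replicate 2 or 3. At 24 h it was 1755 or 1717 without 0 h replicate 2 or 3 and 1525 or 2074 without 24 h replicate 1 or 3.

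**Figure D3:**
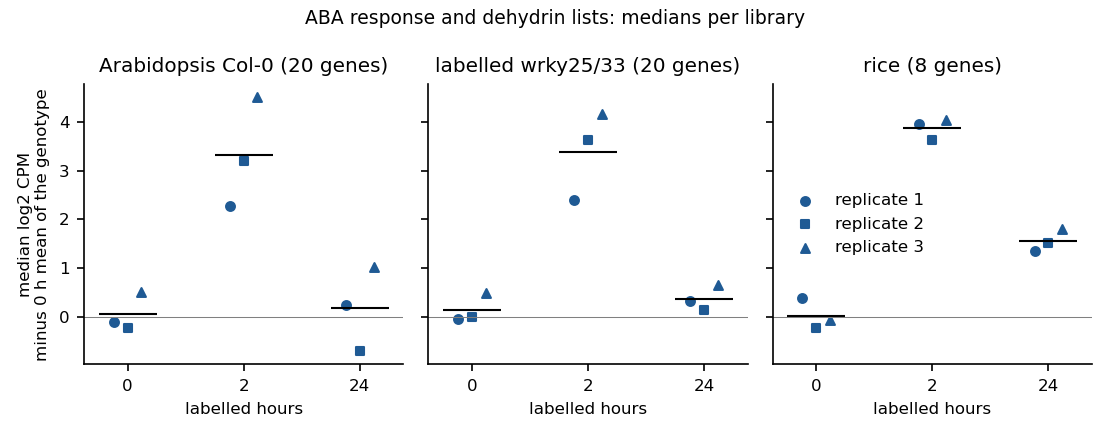
Median log2 CPM of the ABA response and dehydrin list in each library (y axis, log2), at the labelled 0, 2 and 24 h (x axis), with bars at the means. Both Arabidopsis groups are relative to the Col-0 0 h mean, although the axis label names the genotype, and rice to its own 0 h mean. At 2 h the libraries lie between 2.28 and 4.51 in Col-0, 2.39 and 4.16 in the line labelled wrky25/33 and 3.63 and 4.04 in rice, and at 24 h between -0.71 and 1.03, 0.14 and 0.65, and 1.36 and 1.80.

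The comparison of the genotypes asks what the loss of WRKY25 and WRKY33 changes, but neither transcript was called lower in the libraries labelled so. WRKY25 ran from 33.2 to 124 CPM over the 9 libraries labelled wrky25/33 and from 24.7 to 135 CPM in Col-0, and WRKY33 from 20.2 to 164 and from 18.1 to 229 CPM. Their log2 fold changes at 0, 2 and 24 h were 0.16 ± 0.33, -0.06 ± 0.33 and 0.07 ± 0.33 for WRKY25 and -0.22 ± 0.73, 0.18 ± 0.74 and 0.07 ± 0.74 for WRKY33 (adjusted p = 1 for each). WRKY60 (AT2G25000), by contrast, had 6 counts in total over the 9 labelled libraries, 6 of them at 0, and 4832 in Col-0 (12.7 to 34.5 CPM). WRKY18 (AT4G31800) stood at 4.45 to 16.6 CPM against 19.8 to 138 CPM in Col-0 and was lower at 0 h (log2 fold change -2.57 ± 0.34, adjusted p = 0.00179) and 24 h (-2.92 ± 0.36, adjusted p = 0.000764). WRKY40 (AT1G80840) stood at 106 to 399 CPM against 5.11 to 91.1 CPM. It was called higher at 2 h (log2 fold change 4.69 ± 0.85, adjusted p = 0.0321) and 24 h (4.74 ± 0.86, adjusted p = 0.0308). These calls ended at 2 h without any 1 library but labelled replicate 3 (adjusted p from 0.106 to 0.274) and at 24 h without any 1 of the 6 (from 0.0561 to 0.179). The rule for named genes takes these 3, but they were singled out after their values were seen.

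Few other genes set the libraries labelled wrky25/33 apart from Col-0, and the same ones recurred. AT4G24420 was higher in the labelled libraries by 7.56 ± 0.38 at 0 h, 6.69 ± 0.37 at 2 h and 6.73 ± 0.38 at 24 h (adjusted p = 2.3e-08, 7.61e-08 and 9.81e-08). AT5G28030 was higher by 7.01 ± 0.50 at 0 h (adjusted p = 1.38e-06). AT5G28350 was lower at 0 h (log2 fold change -7.26 ± 0.51, adjusted p = 1.38e-06), as was AT4G20480 (-3.71 ± 0.28, adjusted p = 1.99e-06). In total 16 genes were higher and 14 lower at 0 h, 18 and 16 at 2 h, and 18 and 17 at 24 h. Of the 43 genes called at any time 22 were called at all 3 and 43 kept their sign. No list was called between the genotypes at any time by fry. The counts of 34 at 2 h and 35 at 24 h were 64 and 57 with a replicate block. They were 22 at 2 h without Col-0 2 h replicate 3, and 23, 19 and 21 at 24 h without Col-0 replicate 1 or labelled replicate 2 or 3. With replicates 1 and 2 only the counts at 0, 2 and 24 h were 14, 16 and 13, and with replicates 1 and 3 only 11, 8 and 13.

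The salt response was not found to differ between the genotypes. The test of the difference (genotype by salt interaction) called 0 genes in edgeR and in DESeq2 at 2 h and at 24 h, with 80 and 99 genes at an unadjusted p below 0.05 in edgeR. Across the 19316 genes the fold changes of the 2 groups had r = 0.885 (rho = 0.842) at 2 h and r = 0.898 (rho = 0.89) at 24 h, where genes are not independent replicates. At 2 h 630 genes rose in both groups, against 40.1 if the calls were independent, and 379 fell in both, against 16.6. At 24 h 1579 rose in both and 1094 fell in both, with no gene called in opposite directions at either time. Both groups share batches, and how much of this likeness is of the batches was not tested.

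**Figure D4:**
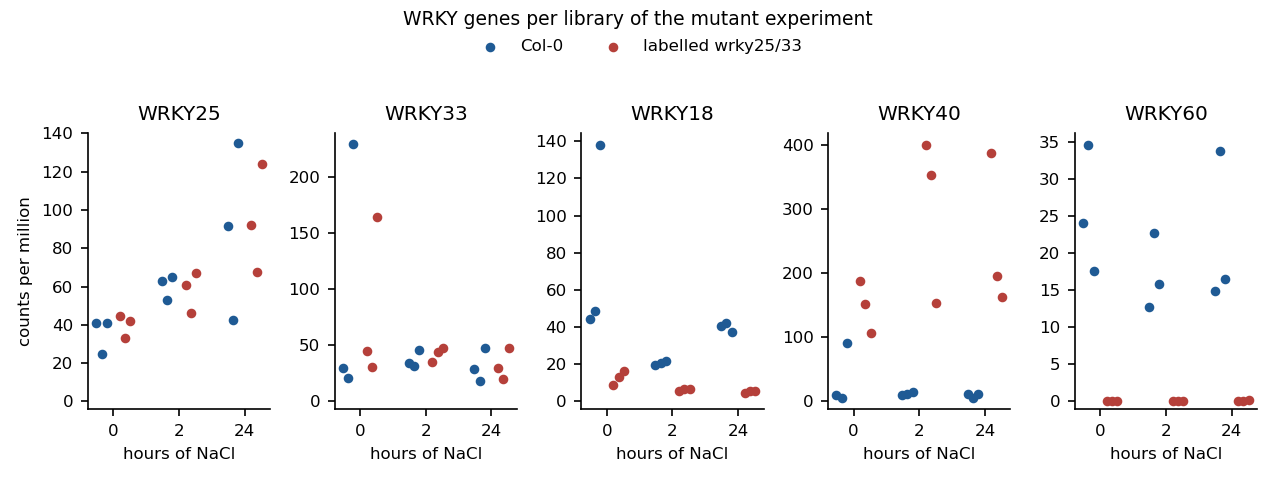
CPM of 5 WRKY genes in each library of the mutant experiment (y axes, linear from 0), by hours of salt (x axes), with 3 libraries per genotype and time. WRKY25 and WRKY33 overlap between Col-0 and the libraries labelled wrky25/33, whereas WRKY60 lies at 0 to 0.146 CPM in the labelled libraries and at 12.7 to 34.5 CPM in Col-0.

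Set side by side, the Arabidopsis experiments shared early genes more than late ones. Over 13671 genes tested in both, fold changes in the time course at 3 h and in Col-0 of the mutant experiment at 2 h had r = 0.626 across genes, and those at 1 h and 2 h had r = 0.553. At 24 h, the time both sampled, r was 0.378 (rho = 0.308), with 60.7% of genes on the same side of 0. There 272 genes rose in both, against 102 if calls were independent, 199 fell in both, against 65.9, and 54 were called in opposite directions. P5CS1 rose at 24 h in both, by 1.73 ± 0.25 in the time course (adjusted p = 0.00184). LHCB1.4 fell at 24 h in the time course (log2 fold change -1.66 ± 0.37, adjusted p = 0.0126, and 0.113 and 0.139 without 0 h or 24 h replicate 2), and stood at 0.44 ± 0.36 in Col-0 of the mutant experiment (adjusted p = 0.417). This r was 0.324 without time course 0 h replicate 1, and 0.423 or 0.322 without Col-0 24 h replicate 1 or 3.

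The rice experiment asks which genes change over 24 h in a cereal. At 2 h dehydrin transcripts rose from near the detection limit. OsRAB16C (OS11G0454000) went from 0.0934 to 11 CPM (log2 fold change 6.80 ± 0.39, adjusted p = 5.06e-05). OsRAB16A (OS11G0454300) rose by 5.47 ± 0.32 (adjusted p = 5.85e-05). It was still higher by 5.00 ± 0.33 at 24 h (adjusted p = 9.85e-05). OsLEA3 (OS05G0542500) rose by 5.69 ± 0.40 (adjusted p = 0.000137). Of 8 rice ABA response genes 7 rose at 2 h (7 up and 0 down adjusted over the list alone; median log2 fold change 3.99, fry adjusted p = 7.6e-06), a call that held with an estimated correlation (adjusted p = 0.00878). At 24 h 5 rose and 1 fell (6 up and 1 down adjusted over the list alone; median 2.08, fry adjusted p = 0.000994, adjusted p = 0.169 with an estimated correlation). Of these 5, OsRAB16C and OsRAB16B (OS11G0454200) lost their calls without 0 h replicate 2 (adjusted p = 0.0747 and 0.0923), 24 h replicate 2 (0.105 and 0.0778) or 24 h replicate 3 (0.0773 and 0.102). OsRAB16B also lost its call without 0 h replicate 3 or 24 h replicate 1 (0.0603 and 0.0786). Of 12 transcription factor and ABA synthesis genes 2 rose at 2 h (fry adjusted p = 0.914). They were OsBZIP23 (OS02G0766700) by 0.94 ± 0.13 and OsNCED3 (OS03G0645900) by 2.94 ± 0.55 (adjusted p = 0.0125 and 0.0441). Both calls ended without 0 h or 2 h replicate 2 (0.0692 and 0.0616 for OsBZIP23, 0.17 and 0.156 for OsNCED3, as adjusted p), and that of OsNCED3 also without 0 h or 2 h replicate 3 (0.0653 and 0.128) or with a replicate block (0.0827). None of them was called at 24 h by edgeR (fry adjusted p = 0.705).

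At 24 h 2 photosynthesis genes rose in rice, and 1 transporter and 1 trehalose gene fell. OsRBCS4 (OS12G0292400), a subunit of the carbon-fixing enzyme, rose by 1.05 ± 0.17 (adjusted p = 0.00741). Of 5 photosynthesis genes 2 rose (2 up and 0 down adjusted over the list alone), with a fry adjusted p of 0.0163 and an adjusted p of 0.4 with an estimated correlation, and none was called at 2 h by edgeR (fry adjusted p = 0.145). The other of the 2, OsRBCS3 (OS12G0291100; 0.79 ± 0.15, adjusted p = 0.0159), lost its call without 0 h replicate 2 (0.052) or 24 h replicate 1, 2 or 3 (0.056, 0.0781 and 0.0575). The sodium transporter gene OsHKT1;5 (OS01G0307500) fell (log2 fold change -1.62 ± 0.40, adjusted p = 0.0371), as did the trehalose enzyme gene OsTPP1 (OS02G0661100; -1.32 ± 0.35, adjusted p = 0.0446). They were the 2 called of 5 on their list (fry adjusted p = 0.325). These calls ended without 0 h replicate 2 (0.0902 and 0.0981), 24 h replicate 2 (0.154 and 0.121) or 24 h replicate 3 (0.143 and 0.095), and for OsTPP1 also without 24 h replicate 1 (0.133). Of genes without a name, OS03G0820500 rose and OS01G0368900 fell at 2 h (log2 fold change 5.53 ± 0.22 and -2.30 ± 0.18, adjusted p = 6.71e-06 and 0.000286). OS04G0206600 rose and OS01G0348800 fell at 24 h (6.43 ± 0.63 and -4.06 ± 0.22, adjusted p = 0.00077 and 4.38e-05). Over 24999 genes tested, 149 rose and 79 fell at 2 h and 1076 and 1071 at 24 h (edgeR, n = 3). DESeq2 called far more at both times, and a fit of only the groups of the contrast far fewer, with the counts given below. The sheet naming these libraries gives their times but not the salt, which comes from the protocol, and codes all 9 libraries Cnt, at 2 and 24 h as at 0 h. The changes are those since 0 h, and the sheet leaves open whether salt made them. With replicates 2 and 3 only, since replicate 1 was the shallowest and bore another library prefix, the totals of 228 and 2147 became 35 and 711. At 2 h the total was 475 or 73 without 0 h replicate 1 or 2 and 99, 75 or 87 without 2 h replicate 1, 2 or 3. At 24 h it was 5064 or 970 without 0 h replicate 1 or 2 and 652, 458 or 613 without 24 h replicate 1, 2 or 3.

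The second Marchantia experiment asks for the liverwort's changes at 2 and 24 h. The locus Mapoly0097s0034 had 0 counts at 0 h and 2474 at 2 h, at least 765-fold higher against a floor of 3 counts over the group, and at least 30.8-fold higher at 24 h. Mapoly0080s0040 rose from 0.287 CPM at 0 h to 4.08 at 2 h (log2 fold change 3.80 ± 0.67, adjusted p = 0.00217) and stood at 106 CPM at 24 h (8.49 ± 0.53, adjusted p = 1.18e-06). Mapoly0037s0118 fell at 2 h and 24 h (log2 fold change -3.48 ± 0.32 and -2.96 ± 0.31, adjusted p = 3.76e-05 and 2.44e-05), as did Mapoly0085s0007 (-2.91 ± 0.53 and -6.78 ± 0.75, adjusted p = 0.00267 and 3.49e-05). Over 9896 genes tested, 1086 rose and 1169 fell at 2 h and 2409 and 2443 at 24 h (edgeR, n = 3). No function is given, since the tables do not pair these loci with names, and the sheet naming the libraries gives times but not the salt. It codes all 9 libraries Crt, at 0 h and later, so it leaves open whether salt made these changes. Replicates of one number resembled each other here. At 2 h the total of 2255 was 3632 with a replicate block. It was 1235 with replicates 2 and 3 only, since replicate 1 at 0 h and other times held up to 27.6% unmapped reads.

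The Marchantia time course asks for the response over 72 h and gave no gene lists by time. By edgeR 0 of 11257 genes were called at any time, although 53 rose and 129 fell at 24 h when only the groups of the contrast were fitted, with 0 at the other times. At an unadjusted p below 0.05 there were 120 at 1 h, 95 at 3 h, 226 at 6 h, 426 at 12 h, 1267 at 24 h, 134 at 48 h and 251 at 72 h. DESeq2 called 1 gene at 6, 12 and 48 h, 2 at 24 and 72 h and 0 at 1 and 3 h. The libraries labelled with one time did not resemble each other, so these calls cannot show whether genes changed with time. Across genes, none of 16 libraries had its labelled partner as the closest library, with a median r of -0.05 between partners and 0.88 between closest libraries. Libraries were closest to one of their labelled group in 10 of 16 cases in the Arabidopsis time course, 7 of 9 in rice and 9 of 9 in the second Marchantia experiment. In the mutant experiment 2 of 18 were. There the others were closest to the library of the same time and batch in the other genotype, so every closest library shared the labelled time. Fold changes at the time labelled 24 h here and at 24 h in the second experiment had r = 0.727 (rho = 0.749) over 9894 genes and 79.9% on the same side of 0. That r was 0.61 or 0.811 without the library labelled 0 h replicate 1 or 2 and 0.672 without 24 h replicate 1. Both labelled groups behind it join unlike libraries, with r = 0.43 between those labelled 24 h and 0.21 between those labelled 0 h. The r of 0.727 therefore does not show a 24 h response seen again.

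**Figure D5:**
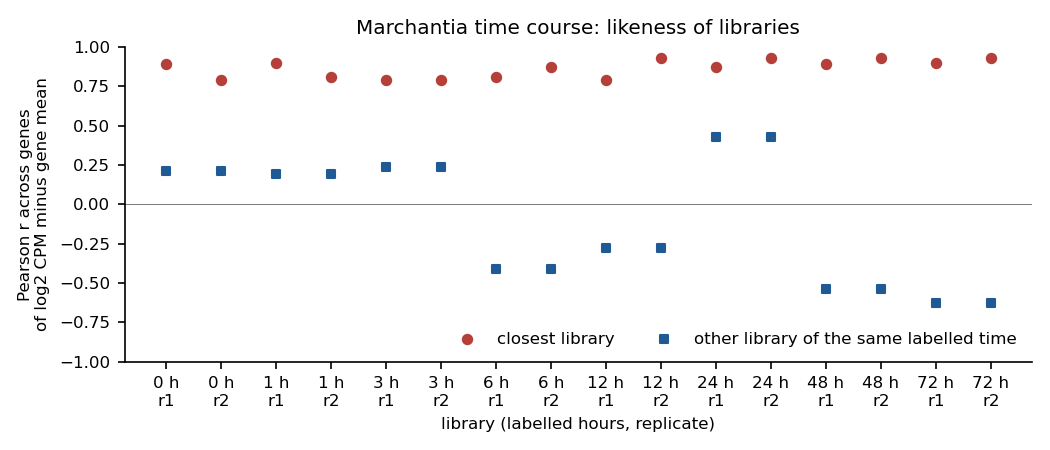
Pearson r across genes of log2 CPM, centred on each gene's mean, between each library of the Marchantia time course and its closest library (circles) or the other library of its labelled time (squares), with libraries on the x axis. Closest libraries reach 0.79 to 0.93, and labelled partners -0.63 to 0.43.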

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

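Every direct contrast between times, test of an explanation and count over splits in this part was chosen after the results were seen. Transcript levels differed between early and late times in each experiment tested by a contrast of the times themselves. In the Arabidopsis time course 4152 genes differed between 72 h and 1 h, 2608 without the 1 h replicate 2 and 1209 with only the groups of the contrast, with the ABA response genes lower later (0 of 17 up and 12 down, median -2.70, fry adjusted p = 0.000699, adjusted p = 0.549 with an estimated correlation). ABA synthesis and signalling (0 up and 8 down of 14; 0.00257, and 0.625 with an estimated correlation), the clock (0 and 7 of 10; 0.00468 and 0.625), heat shock (0 and 4 of 7; 0.0206 and 0.671), photosynthesis (0 and 27 of 31; 0.0398 and 0.693) and proline and osmolytes (2 and 6 of 13; 0.00468 and 0.671) were lower later too. Senescence genes were higher later (2 and 0 of 5; 0.0364 and 0.671).

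In the mutant experiment 2577 genes differed between 24 h and 2 h in Col-0 and 2384 in the line labelled wrky25/33, or 5390 and 5100 with a replicate block. The Col-0 count was 1530 or 1403 without 2 h replicate 2 or 3, and 1694 or 1407 without 24 h replicate 1 or 3. That of the labelled line was 1417 or 1415 without 2 h replicate 2 or 3, and 1385 or 1559 without 24 h replicate 1 or 2. With replicates 1 and 2 only the counts were 698 and 805, with replicates 1 and 3 only 1890 and 1184, and with only the groups of the contrast 1031 and 2447. ABA response genes were lower later in Col-0 (17 of 20 down, median -3.60) and in the labelled line (16 of 20, median -3.78), each with a fry adjusted p of 0.000699 and 0.386 with an estimated correlation. ABA receptors were higher later (4 of 9 up and 1 down in Col-0, 0.00468 and 0.625 with an estimated correlation; 3 and 0 in the labelled line, 0.00885 and 0.625). ABA synthesis genes (10 of 21 down in Col-0, 0.0206 and 0.671; 8 in the labelled line, 0.0438 and 0.671) and suberin genes (1 of 8 up and 4 down in each, 0.00533 and 0.637 in Col-0, 0.0364 and 0.671 in the labelled line) were lower later. Jasmonate genes were lower later in the labelled line (1 of 15 up and 5 down, 0.0205 and 0.671). In rice 514 genes differed between 24 h and 2 h, 126 to 225 without any 1 of the 6 libraries, 62 with replicates 2 and 3 only, 1130 in DESeq2 and 1786 with only the groups of the contrast, and 6 of 8 ABA response genes were lower later (median -2.04, fry adjusted p = 0.000699, adjusted p = 0.15 with an estimated correlation). In the second Marchantia experiment 4239 genes differed between 24 h and 2 h.

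The first pattern to follow up is that WRKY25 and WRKY33 were not lower in the libraries labelled wrky25/33. Another WRKY mutant line under this label cannot be told apart: 1 other WRKY gene, WRKY60, was called lower at all 3 times, with 6 counts against 4832, but this is the value that prompted the explanation and no test of it. WRKY18 (4.45 to 16.6 CPM against 19.8 to 138 in Col-0) and WRKY40 (106 to 399 against 5.11 to 91.1) also differed. They too were singled out after their values were seen. Chromosome segments of another origin may account for most of the other differences, since 38 of the 43 genes called lie within 100 tested loci of another called gene (mean of 10000 random sets 14.97, highest 29, permutation p = 1e-04, one-sided, the smallest they can give). They gather in 3 stretches, with 10 of 253 genes from AT1G78 to AT1G80, which holds WRKY40, 17 of 383 from AT4G20 to AT4G24 and 9 of 41 in AT5G28. These stretches lie on chromosomes 1, 4 and 5, whereas WRKY25 (AT2G30250) and WRKY33 (AT2G38470) lie on chromosome 2. On chromosome 2 the called genes were AT2G08735 and WRKY60 (AT2G25000), so the stretches are not segments next to WRKY25 or WRKY33. Insertions that leave WRKY25 and WRKY33 transcripts cannot be told apart from an intact gene, since the largest change of the 2 genes was 0.22 (log2) and counts per gene hold no position within it.

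The second pattern is that libraries of one labelled time in the Marchantia time course are unlike. Wrong time labels on libraries are a candidate explanation: all 16 libraries fall into 8 mutual closest pairs with r of at least 0.79 across genes, and no labelled pair exceeds 0.43. Of these 8 pairs 6 lie 6 sheets apart in the deposited order and 2 lie 2 apart, and none joins libraries of 1 labelled time. The pairing follows the deposited order. Sheets 1 to 6, labelled 0, 1, 3, 6, 12 and 24 h of replicate 1, pair in turn with sheets 7 to 12. Those bear the labels 48 and 72 h of replicate 1 and 0, 1, 3 and 6 h of replicate 2. Sheets 13 and 14, labelled 12 and 24 h of replicate 2, pair with sheets 15 and 16, labelled 48 and 72 h. Shallow or noisy libraries are argued against, as the closest libraries differ by a median of 0.124 (log2), below the 0.218 of labelled replicates in the Arabidopsis time course. A lack of any change between libraries is argued against: single libraries line up with the 24 h changes of the second experiment with r from -0.75 to 0.69. Closest libraries had near values of this r: -0.73 and -0.75, -0.53 and -0.53, -0.44 and -0.41, and -0.22 and -0.23. The other closest pairs had 0.16 and 0.04, 0.68 and 0.69, 0.56 and 0.53, and 0.61 and 0.58. Whether salt made these changes cannot be told, because the sheet of the second experiment codes its libraries alike and does not name salt. No biological explanation was tested, and the labels were kept.

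The third pattern is that stress transcription factors were high in the 0 h libraries of replicate 3 of the mutant experiment. Their list medians were 1.41 and 1.5 (log2, relative to the Col-0 0 h mean, replicate 3 included) against -1.19 to -0.1 in the other 0 h libraries. A mix-up of 0 h with 2 h libraries is argued against: the lower of the 2 medians, 1.41, exceeds the 1.07 of the highest 2 h library, and the dehydrin list stood at 0.51 and 0.48 there against at least 2.28 at 2 h. Handling of the seedlings before the harvest of that batch may be the cause, since both genotypes show it (up to 1.5), but it cannot be told apart from other differences of that batch because the labels do not describe the harvests.

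Over other splits of the same 6 libraries, 10 in all and too few for a share under 0.05, the real split called the most genes in each contrast with 0 h of 3 libraries against 3. The real values of 1851 and 3616 in Col-0, 1131 and 3571 in the labelled line, 2147 in rice at 24 h, and 2255 and 4852 in the second Marchantia experiment stand against a highest other of 0 in each, and 228 in rice at 2 h against 1. The later against earlier contrasts of 2577, 2384, 514 and 4239 genes also stand against 0, as do the genotype contrasts of 30 at 0 h and 34 at 2 h (1 split of 10 as large, the real one, in every case so far). For the genotypes at 24 h the real 35 was matched by 2 of 10 splits, itself included: the other split, which joins labelled replicate 1 with Col-0 replicates 1 and 3, called 160, several times the real count. It points to a structure of these libraries, and it has both libraries of batch 1 on one side. Of the 10 splits 4 part the 2 libraries of every batch, as the real one does, and the other 3 called 0. With the replicate block the real split called 57. For the interactions the splits decide nothing, since with a real count of 0 all 100 of 100 drawn are as large. Of these 5 called more than 0 genes at 2 h and 2 at 24 h, with a highest of 952 and 280.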

How the results depend on the processing

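Named genes and list calls kept their direction under every alternative run. For named genes this was nearly fixed beforehand, since in almost all their called values the groups do not overlap. What moved was whether genes and lists passed. Of 658 called values of named genes, 658 stayed called in DESeq2, 656 with RLE scaling, 642 with no filter, 657 with a replicate block and 525 of 644 with only the groups of the contrast, where fewer libraries set the spread. Without 1 library 2149 of 3202 stayed called. In fits chosen after seeing the data, 78 of 245 stayed called with replicates 1 and 2 only and 147 of 245 with replicates 1 and 3 only in the mutant experiment, and 28 of 40 with replicates 2 and 3 only in rice and the second Marchantia experiment. With RLE and with no filter every count of genes stayed within 1.5 times. Of 40 list calls, 40 held with fry on RLE values, 34 with the replicate block (the other 6 are of the Arabidopsis time course), 39 with camera at its preset correlation of 0.01 and 1 with an estimated correlation. Depth limits what can be said of genes with few counts, which the filter leaves out, but it was not varied. In counts simulated for rice at 24 h, 2-fold changes were found in 47.8% of cases.

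With only the groups of the contrast the Arabidopsis time course counts became 1358 at 1 h, 2011 at 6 h, 995 at 12 h and 1363 at 72 h, Col-0 at 24 h 61, the genotypes 10 at 0 h and 15 at 24 h, rice 49 and 802, and the Marchantia time course at 24 h 182. DESeq2 called 1074 in the Arabidopsis time course at 12 h, 1844 in the labelled line at 2 h, 46, 57 and 55 between genotypes at 0, 2 and 24 h, 832 and 3704 in rice, and 1, 1, 2, 1 and 2 in the Marchantia time course at 6, 12, 24, 48 and 72 h; its share of false calls on simulated data was the higher in each comparison, up to 43.4% in that time course. With the replicate block Col-0 gave 4823 and 6895, the labelled line 3475 and 7021, the genotypes 64 at 2 h and 57 at 24 h, and the second Marchantia experiment 3632 at 2 h. With replicates 1 and 2 only, an alternative chosen after seeing the data like the next ones, Col-0 gave 473 and 349, the labelled line 173 and 441, and the genotypes 14, 16 and 13; with replicates 1 and 3 only Col-0 gave 631 at 2 h, the labelled line 345 and 2193, and the genotypes 11, 8 and 13. With replicates 2 and 3 only rice gave 35 and 711 and the second Marchantia experiment 1235 at 2 h. The interactions stayed at 0 throughout.

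Without 1 library the Arabidopsis time course gave 1201 to 1704 at 1 h, 1230 to 1643 at 3 h, 184 to 369 at 6 h, 112 to 299 at 12 h, 406 to 960 at 24 h, 1279 to 2172 at 48 h and 1431 to 3663 at 72 h. Col-0 gave 820 to 1354 at 2 h and 1650 to 6052 at 24 h, the labelled line 562 to 935 and 1525 to 3082, the genotypes 22 to 29 at 2 h and 19 to 27 at 24 h, and rice 73 to 475 and 458 to 5064. A time left with 1 library was assumed to vary like the other times. Apart from fewer libraries or genes, the cause of these moves was not tested. List calls numbered 42 with the preset and 0 with an estimated correlation in the time course (23 by fry), 38, 0 and, with the replicate block, 27 in the mutant experiment (14 by fry), and 1 with an estimated correlation in rice (3 by fry). The r between the Arabidopsis experiments at 24 h was 0.331 with genes of at least 5 CPM and 0.322 to 0.423 without 1 library, and that between the Marchantia experiments 0.61 to 0.811 without 1 library.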

Other observations

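These values belong to genes of the Arabidopsis time course not described so far. EXPA8 (AT2G40610), an expansin, rose at 6 h (log2 fold change 2.44 ± 0.24, adjusted p = 0.000289) and was lower at 72 h (-1.89 ± 0.25, adjusted p = 0.000547). CBP60G (AT5G26920), a regulator of salicylic acid synthesis, rose at 1 h (1.77 ± 0.37, adjusted p = 0.00575), and ICS1 (AT1G74710), the synthesis enzyme, was lower at 24 h (-0.96 ± 0.16, adjusted p = 0.00352). UPOX (AT2G21640), a marker of oxidative stress, rose at 24 h (2.67 ± 0.41, adjusted p = 0.0023). ACO4 (AT1G05010), the last enzyme of ethylene synthesis, was lower at 48 h (-1.89 ± 0.24, adjusted p = 0.000389), while JAZ10 (AT5G13220), a jasmonate repressor, rose at 72 h (1.78 ± 0.35, adjusted p = 0.00439).

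In the mutant experiment NAC019 (AT1G52890), a stress transcription factor, rose at 2 h in Col-0 (5.25 ± 0.84, adjusted p = 0.00119) and in the labelled line (4.05 ± 0.80, adjusted p = 0.00682). CAX3 (AT3G51860), a vacuolar calcium transporter, rose at 24 h in both (2.99 ± 0.57 and 2.99 ± 0.57, adjusted p = 0.00334 and 0.00355), and SUS3 (AT4G02280), which splits sucrose, rose at 24 h in both (2.11 ± 0.37 and 2.40 ± 0.37, adjusted p = 0.00206 and 0.00113). EDS1 (AT3G48090), an immune regulator, was lower at 24 h in Col-0 (-1.39 ± 0.31, adjusted p = 0.00776).

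Of 51 WRKY genes tested 3 were called between the libraries labelled wrky25/33 and Col-0. Drawn independently the called genes would hold 0.11, but 36 of the 43 lie in 3 stretches, 1 of which holds WRKY40, and no test was made. In rice 13 of the features called at 24 h and 1 at 2 h bear identifiers of another annotation.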
